A study of Oncorhynchus mykiss with 12 samples.

How the data were processed

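Small RNA from the liver of 12 adult rainbow trout was sequenced on an Illumina GAIIx. Per the labels, RNA was taken from flash-frozen liver with Trizol, and libraries were made from 1 ug of total RNA with a TruSeq RNA kit. The labels name the groups and the fish, and no batch, run or date.

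A first deposited table gave, for each library, a count of raw reads, of reads holding the 3′ adapter, of inserts under 15 nt, of inserts over 32 nt and of mappable reads. A second deposited table gave 1 line per miRNA sequence, with an estimated count per library (reads shared between sequences were split into fractions) and a normalized signal per library. Of its 1696 sequences, 988 carried known miRNA names, with the prefix of the fish species they were matched to, and 708 were predicted candidates with names starting in PC. The names also carry the authors' marks for length and base differences. In the estimated counts, 85.1% of values were exactly whole. The authors' normalized signal equalled the estimated count divided by 1 library size parameter per library, with zeros written as 0.001. It was not used for tests. The submitters' processing notes name Bowtie 1.1.1 without its role. The genome build, the miRNA database release and the division of shared reads are not given in the sources used here, and no miRNA coordinates were analysed here. Members of let-7, miR-19 and other families differ by 1 or a few bases, so the split of reads between them is uncertain.

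Groups were taken from the labels: fasted (fish 7, 8, 10 and 13), refed without carbohydrate (noCHO, fish 20, 21, 31 and 33) and refed with a high-carbohydrate meal (highCHO, fish 38, 45, 49 and 50). Estimated counts were rounded and tested with edgeR 4.0.16 in R 4.3.3, with TMM normalization and the edgeR expression filter by group, which left 340 sequences (291 known, 49 candidates) with 99.87% of counts. All 12 libraries entered 1 quasi-likelihood fit with 9 residual degrees of freedom and 4 contrasts: noCHO against fasted, highCHO against fasted, highCHO against noCHO, and the mean of both refed groups against fasted. Tests were two-sided, adjusted by Benjamini-Hochberg over the sequences tested, with a threshold of 0.05. Standard errors (SE) were derived from the fold change and its F statistic. Levels are CPM after TMM scaling, given as mean ± SD of 4 libraries unless stated. The biological coefficient of variation was 0.411.

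Lists of miRNA families were fixed before the data were examined, as were the groups, contrasts, tests, thresholds and the first group of alternatives below. The 16 lists were hepatocyte, glucose and insulin, lipid and cholesterol, trout postprandial candidates, let-7, miR-17-92 and relatives, erythrocyte, leukocyte, fish interferon-induced pair, endothelial, fibroblast and smooth muscle, skeletal and cardiac muscle, epithelial, pancreas, neural, and stress and hypoxia. A sequence belonged to a list by the family number in its name. The 15 lists with at least 3 tested sequences were compared with all other tested sequences by camera (limma 3.58.1) on log2 CPM with a prior count of 1 and a preset correlation of 0.01, adjusted over the lists. The same test with an estimated correlation was run beside it. So was fry, which asks a different question: whether a list changed at all, without reference to the other sequences. Lists share members: 7 of the 20 hepatocyte sequences, 11 of the 27 glucose and insulin sequences and all 16 trout postprandial candidates stand in another list too. The lists of other cell types hold miRNAs that liver also expresses.

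Named sequences followed a rule. For each comparison it takes up to 10 higher and up to 10 lower sequences past the threshold in order of adjusted p, with candidates named only among the first 5 of a direction. Where fewer than 10 passed, sequences with the smallest unadjusted p are added up to 10 and stated as not passing. It adds the 4 most abundant members of each list, the 10 most abundant sequences, and the families miR-122, miR-33, miR-103, miR-107, miR-143 and miR-29. Any other name is given as chosen after its values were seen.

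Library composition was compared by two-sided exact permutation tests of 4 against 4 libraries (70 arrangements, smallest p 0.0286), adjusted over 24 comparisons. The table held 0 sample columns outside the groups, and no libraries were identical. Counts per library were 197684 to 3057706. At the lowest depth, 1 CPM is 0.198 counts, so sequences of a few CPM rest on few reads there. Intervals for shares of single libraries are 95% exact (Clopper-Pearson) and cover counting error only, since reads without molecular identifiers are not independent molecules.

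The alternatives were other scalings (median-ratio, sample total), no filter or a mean count of at least 100, DESeq2 1.42.0, a robust fit, only the groups compared, sequences summed by name, known names only, and each library left out. Added after seeing the data were a term for 2 sets of libraries, fits within a set, a term for the percentage of short inserts, leaving out highCHO fish 38 and 49 together, the authors' size parameters, and leaving out the let-7 sequences with an A19C difference. The 2 sets were found at the widest gap in the share of let-7a-like reads with that difference. The fit was also tested on simulated data. Over 20 simulations at the sizes of the highCHO against fasted comparison, with 200 of 1696 sequences changed, it called 26.8% of tested 2-fold changes and 80.7% of 4-fold changes, and 3.16% of its calls were false. A let-7 list shifted by 0.5 on the log2 scale was called in 20 of 20 simulations, with 3 calls of other lists. In the first 20 simulations only the highCHO group was changed, so noCHO against fasted held 0 changed sequences. That contrast called 0 sequences and 1 list. Sequences were simulated as independent, whereas the let-7 list had an estimated correlation of 0.230 in the data. The list results of the simulations therefore do not carry over to these data.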

Results

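Liver miRNA was profiled in adult rainbow trout, a carnivorous fish with poor tolerance of dietary glucose, after a 4-day fast and after acute refeeding with a meal holding no carbohydrate (noCHO) or a high level of carbohydrate (highCHO). Each group held 4 fish, 1 library per fish. Counts assigned to miRNA sequences averaged 1.38 ± 0.824 M per library in fasted fish, 1.83 ± 0.931 M in noCHO fish and 1.08 ± 0.644 M in highCHO fish (SD, n = 4 each). The lowest was 197684 (highCHO fish 49) and the highest 3057706 (noCHO fish 33).

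The most abundant sequence in all 3 groups was dre-miR-122_R-1, the hepatocyte miRNA miR-122, which made up 27.5 ± 0.904% of counts in fasted fish, 32.6 ± 2.57% in noCHO fish and 26.1 ± 3.71% in highCHO fish (SD, n = 4). All 4 noCHO fish lay above all 4 fasted fish in this share (two-sided exact permutation p = 0.0286, adjusted 0.114), although the fitted change of miR-122 itself did not pass (log2 0.45, SE 0.19, adjusted p = 0.598). Next came dre-miR-100-5p with 192750 ± 24548, 211080 ± 64295 and 252030 ± 137300 CPM in the fasted, noCHO and highCHO groups. Fasted means of dre-miR-30e-5p_R+2, dre-miR-199-5p, ssa-miR-146a-5p and dre-let-7a were 38112, 37010, 34801 and 29047 CPM. Those of dre-miR-148_R-1, fru-miR-21, ssa-miR-30b-5p_R-4 and ipu-miR-192 were 25021, 23968, 21376 and 20370 CPM.

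The libraries themselves differed between groups. Inserts under 15 nt made up 9.59 ± 2.02% of adapter-containing reads in fasted fish, 9.70 ± 2.87% in noCHO fish and 21.2 ± 7.94% in highCHO fish, with no overlap between highCHO and either other group. The miRNA share of mappable reads was 44.8 ± 1.20%, 50.0 ± 4.71% and 34.0 ± 7.54% in the same order, again without overlap. Raw reads were higher in highCHO than in fasted fish (8.85 ± 0.801 against 7.41 ± 0.744 M). Of 24 comparisons of library composition, 6 had no overlap, each with a two-sided exact permutation p = 0.0286, the smallest that 4 against 4 allows, and an adjusted p = 0.114. Chance gives no overlap in 2.86% of comparisons.

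A let-7 sequence, dre-let-7c-5p_1ss19GC, carries an A19C difference from let-7a (positions from 1 at the 5′ end of let-7a). Its share of let-7a-like reads divided the libraries into 2 sets. In set 1 (fasted fish 7, 8, 10 and 13 and noCHO fish 20 and 21) the share was 0.942 to 1.42%, and in set 2 (noCHO fish 31 and 33 and all 4 highCHO fish) 3.32 to 3.81%. Raw reads followed the same division without overlap, at 6.37 to 7.95 M in set 1 and 8.10 to 9.80 M in set 2. The candidate PC-5p-4045_211, chosen after its values were seen, had 8 to 42 counts in each library of set 1 and 0 in each of set 2. Fasted and highCHO fish share no set, so that comparison has no within-set value, and its value with the set as a term rests on the noCHO fish, 2 in each set.

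**Figure D1:**
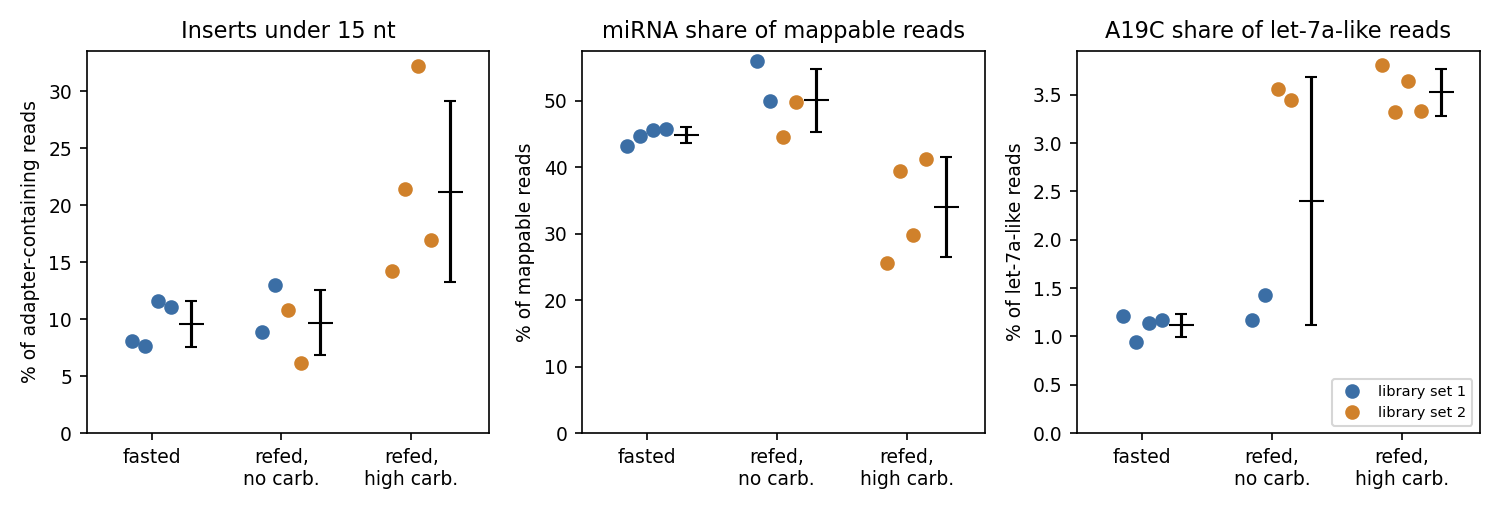
Library composition by group: percentage of adapter-containing reads with inserts under 15 nt (left), miRNA share of mappable reads in percent (middle) and A19C share of let-7a-like reads in percent (right). Points are libraries, coloured by library set, and bars give mean and SD (n = 4). Short inserts reach 14.2 to 32.2% in the highCHO libraries.

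The first comparison asks what a meal without carbohydrate does to liver miRNA after a fast. No single miRNA passed in edgeR (DESeq2 called 2). The let-7 family, conserved miRNAs tied to differentiation and glucose metabolism, rose as a list with camera (adjusted p = 2.49e-06). With an estimated correlation the list did not pass (adjusted p = 0.517), nor with fry (0.335). Of its 22 sequences 19 were higher in noCHO fish, with a median log2 change of 0.32. Its members included fru-let-7e (7278 ± 756 CPM fasted, 11379 ± 1782 noCHO; log2 0.64, SE 0.20), dre-let-7g (4361 ± 769 and 6481 ± 688; log2 0.57, SE 0.19) and dre-let-7i (701 ± 173 and 1182 ± 295; log2 0.75, SE 0.25). The leukocyte list fell with camera (11 of 13 sequences lower, median −0.33, adjusted p = 0.0257), but not with an estimated correlation (adjusted p = 0.727). Its most abundant members, ssa-miR-146a-5p and ssa-miR-146d-5p, had log2 changes of −0.45 (SE 0.35) and −0.28 (SE 0.33), dre-miR-142a-5p −0.34 (SE 0.23) and dre-miR-146b_L+1_1ss23GT −0.39 (SE 0.36).

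In edgeR with all libraries no let-7 sequence passed over all sequences, and 5 were higher when adjusted over the list alone. DESeq2 called dre-let-7c-5p_1ss19GC, as did edgeR without noCHO fish 20. The let-7 list passed with camera with the library set as a term (median 0.45, adjusted p = 4.45e-05), within set 1 (median 0.46, adjusted p = 0.000630) and without the A19C sequences (21 sequences, adjusted p = 2.49e-05). The leukocyte list was lost with the set as a term (median −0.39, adjusted p = 0.124) and within set 1 (median −0.39, 0.0938). It was also lost without fasted fish 7 (0.269) or 8 (0.0571) and without noCHO fish 20 (0.229) or 33 (0.320). No leukocyte sequence passed over all sequences or adjusted over the list alone. The erythrocyte list, with all 5 sequences lower (median −0.32, adjusted p = 0.280), passed downward without fasted fish 13 (0.0288) or noCHO fish 31 (0.0279), the noCHO fish with the highest dre-miR-451_R-1 (2027 CPM).

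Over all 340 sequences edgeR called 0, with 23 at an unadjusted p under 0.05 and a smallest adjusted p of 0.174. DESeq2 called 2, dre-let-7c-5p_1ss19GC and ipu-miR-7550_L-1R-1. Without noCHO fish 20 edgeR called the same 2. The 10 smallest unadjusted p belonged to these 2 (log2 1.36, SE 0.29, and 1.66, SE 0.43), fru-let-7e, dre-let-7g, dre-let-7i, pol-let-7a-3p_R+1_1ss3AG (0.96, SE 0.30), ssa-miR-181a-4-3p (0.90, SE 0.29), dre-miR-181b-5p_R+1 (0.54, SE 0.19), ola-mir-19a-p3 (−2.94, SE 1.01) and ola-miR-101b-5p (−0.71, SE 0.25). None of these passed in edgeR. Within set 1, with 2 noCHO and 4 fasted fish, 0 were called and 44 had an unadjusted p under 0.05; with the set as a term the numbers were 0 and 40. Within set 1, dre-let-7c-5p_1ss19GC had a log2 change of 0.72 and ipu-miR-7550_L-1R-1 1.12.

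The second comparison asks what a high-carbohydrate meal does relative to fasting. In highCHO fish, 4 of the 7 miR-19 sequences passed, each 2- to 3-fold lower. The miR-19 family is part of the miR-17-92 cluster, known for its role in proliferation, but the genomic origin of these sequences was not analysed. Of the 7, 6 were lower and 1 was higher. ssa-miR-19c-3p_R-1 went from 274 ± 49.8 to 117 ± 13.8 CPM (2.33-fold lower; log2 −1.22, SE 0.22, n = 4 and 4) and dre-miR-19a-3p_L+1R-2 from 716 ± 172 to 278 ± 37.3 CPM (2.58-fold lower; log2 −1.36, SE 0.25). Higher were ssa-miR-145-3p_L+2R-1, the 3p arm of a smooth-muscle miRNA, at 9558 ± 1672 against 3210 ± 824 CPM (2.98-fold, log2 1.57, SE 0.22), and dre-let-7d-5p at 290 ± 54.9 against 158 ± 16.1 CPM (1.84-fold, log2 0.88, SE 0.20). With the library set as a term, ssa-miR-145-3p_L+2R-1 did not pass in edgeR (log2 1.43, SE 0.39, adjusted p = 0.0724). ola-miR-145_L+1R+4, of the other arm and named after its values were seen, had a change of 0.17 (SE 0.37). In all, 21 sequences of 340 passed, 11 higher and 10 lower, from 11 named families and 1 candidate, and 92 had an unadjusted p under 0.05. Over the 12 fits leaving out each library, dre-miR-27b-3p_R-1 passed in 1 and ssa-miR-30e-5p, ssa-miR-128-1-5p_1ss12CT, dre-miR-19d-3p_1ss13TA and dre-miR-101a in 2 each. ola-miR-101b-5p and fru-miR-101b_2ss21AC22GT passed in 4 each, dre-miR-429a in 6, dre-miR-722_L-2 in 7 and the other 12 in 9 or more.

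Of the 24 sequences of miR-17-92 and relatives, 18 were lower (median −0.49) and the list fell with camera (adjusted p = 0.00335; adjusted p = 0.250 with an estimated correlation, 0.00285 with fry). All 4 that passed over all sequences were miR-19: the pair above, dre-miR-19c-3p_1ss23GT (log2 −1.58, SE 0.29) and dre-miR-19d-3p_1ss13TA (−1.11, SE 0.29). Adjusted over the list alone, 7 were lower and 1 higher. The abundant members ssa-miR-92a-3p, ssa-miR-92b-3p, dre-miR-92a-3p_R+1 and dre-miR-25-3p did not pass (log2 0.15, 0.32, 0.01 and −0.04, SE 0.13, 0.22, 0.15 and 0.17). For the list, the library set as a term gave a median of −0.48 and an adjusted p of 0.0455. These libraries also had the higher short-insert percentage, and with that as a term the median was −0.38 and the adjusted p 0.0112.

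The let-7 list rose with camera, with 18 of 22 sequences higher and a median of 0.36 (adjusted p = 7.32e-04). It did not pass with an estimated correlation (adjusted p = 0.657) or with fry (0.0601). Those that passed were dre-let-7d-5p, pol-let-7a-3p_R+1_1ss3AG (96.4 ± 32.5 to 262 ± 39.4 CPM; log2 1.44, SE 0.30) and dre-let-7c-5p_1ss19GC (327 ± 58.3 to 1520 ± 164 CPM; log2 2.22, SE 0.30); adjusted over the list alone the number was also 3. dre-let-7c-5p_1ss19GC is the sequence that defined the sets, and with the set as a term its change was 1.12 (SE 0.33, adjusted p = 0.0906), a value that its own use in the definition makes circular. dre-let-7a itself did not pass (0.52, SE 0.18, adjusted p = 0.0902), nor did hhi-let-7j (−0.02, SE 0.16). For the list, the set term gave a median of 0.72 and an adjusted p of 0.00135, and without the A19C sequences the adjusted p was 0.00343.

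Among miRNAs studied in lipid and cholesterol handling, 4 of 41 rose and 1 fell. The risers were ssa-miR-27d-5p (60.1 ± 12.3 to 416 ± 308 CPM; log2 2.78, SE 0.58), dre-miR-27b-3p_R-1 (4227 ± 599 to 6747 ± 1568 CPM; log2 0.67, SE 0.18), ssa-miR-128-2-5p (6.86 ± 3.32 to 32.2 ± 20.2 CPM; log2 2.21, SE 0.46) and ssa-miR-128-1-5p_1ss12CT (4.40 ± 2.83 to 12.9 ± 3.85 CPM; log2 1.52, SE 0.41). dre-miR-27b-3p_R-1 was named after its values were seen, as was dre-miR-27d_R-1_2ss11CT20TG, of the other arm of miR-27d. The latter had a change of 0.04 (SE 0.27), with 7031 ± 1391 CPM in fasted and 7208 ± 1790 CPM in highCHO fish. Of the 5 miR-128 sequences, 3 were higher and 2 lower. ssa-miR-30e-5p fell by 0.67 on the log2 scale (SE 0.17; 3209 ± 238 to 2019 ± 350 CPM), while the far more abundant dre-miR-30e-5p_R+2 had a change of −0.01 (SE 0.16). Adjusted over the list alone, 5 were higher and 1 lower. The list as a whole did not pass (median 0.14, adjusted p = 0.466).

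In the hepatocyte list the 3 of 20 sequences that fell were all miR-101: ola-miR-101b-5p (511 ± 102 to 257 ± 41.8 CPM; log2 −0.99, SE 0.26), dre-miR-101a (669 ± 107 to 380 ± 91.1 CPM; log2 −0.81, SE 0.21) and fru-miR-101b_2ss21AC22GT (2362 ± 496 to 1002 ± 274 CPM; log2 −1.24, SE 0.34). Adjusted over the list alone 3 were lower. The other abundant members dre-miR-122_R-1, dre-miR-148_R-1 and ipu-miR-192 had changes of 0.15 (SE 0.19), 0.07 (SE 0.33) and 0.50 (SE 0.31), and the minor-arm ssa-miR-122-2-3p_1ss10AT −0.18 (SE 0.19). The list's median (0.11) and mean (0.09) were positive while its test pointed down (adjusted p = 0.466). Without highCHO fish 38, which held 53161 CPM of ipu-miR-192 against at most 23309 CPM in the other 3 highCHO fish, the median was −0.20 (adjusted p = 0.108). In the glucose and insulin list, fru-miR-152, of the miR-148 family, fell (9537 ± 682 to 5307 ± 1211 CPM; log2 −0.85, SE 0.17), the only one of 27 past the threshold over all sequences. Adjusted over the list alone 1 was higher and 5 lower. ssa-miR-26a-5p, ccr-miR-143 and dre-miR-181a-5p, its other abundant members, had changes of 0.32 (SE 0.17), 0.53 (SE 0.25) and 0.02 (SE 0.19), and the list had a median of −0.13 (adjusted p = 0.466).

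Outside these lists, dre-miR-722_L-2, a miRNA described in fish, fell (7149 ± 775 to 3963 ± 620 CPM; log2 −0.85, SE 0.19). The 16-nt sequence ipu-miR-7550_L-1R-1 rose (89.2 ± 44.6 to 527 ± 88.2 CPM; log2 2.55, SE 0.44), as did the 18-nt candidate PC-5p-219_12291 (CCGTGGACGTTCCCGTGG; 448 ± 58.3 to 1739 ± 468 CPM; log2 1.96, SE 0.25). The epithelial miRNA dre-miR-429a rose (29.2 ± 10.0 to 149 ± 97.7 CPM; log2 2.36, SE 0.61), and with the set as a term its change was 0.48 (SE 0.88, adjusted p = 0.800). Adjusted p of the 21 sequences ran from 0.00119 (dre-let-7c-5p_1ss19GC) to 0.0496.

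The families picked in advance from trout feeding studies, miR-122, miR-33, miR-103, miR-107, miR-143 and miR-29, had no member past the threshold, and their list of 16 had a median of −0.08 (adjusted p = 0.466; mean −0.24). All 5 miR-29 sequences were lower (median −1.11, smallest adjusted p = 0.0723), the most abundant being ssa-miR-29b-2-5p_L-2 at 870 ± 378 and 370 ± 68.7 CPM (log2 −1.23, SE 0.41). ssa-miR-29b-3p, named after its values were seen, passed with the set as a term (log2 −2.04, SE 0.43, adjusted p = 0.0270). Family medians were 0.16 for miR-122 (4 sequences), 0.14 for miR-33 (3; the most abundant, ssa-miR-33b-3p, at −0.28), 0.04 for miR-103 (fru-miR-103 alone), −0.26 for miR-107 (dre-miR-107a-3p_R-1 alone) and 0.27 for miR-143 (2). Scaling to the sample total took the median of all sequences from 0.03 to −0.19 here, from 0.02 to −0.17 for noCHO and from 0.03 to −0.17 for both refed groups against fasted. It turned the miR-122, miR-33 and miR-103 medians to −0.08, −0.05 and −0.22.

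Lists of other cell types did not pass in this comparison. The pancreas list had a median of 2.94 (5 sequences, adjusted p = 0.466; 3 higher adjusted over the list alone), and without highCHO fish 38 a median of −0.58. Fish 38 held 8261, 2500, 1812 and 204 CPM of ssa-miR-216b-5p, dre-miR-375, dre-miR-216b and fru-miR-7_R+2, against at most 78.6, 162, 26.6 and 155 CPM in the 11 other libraries. Medians were 0.76 for epithelial (9 sequences, 1 called higher, 3 adjusted over the list alone; adjusted p = 0.466), 0.09 for fibroblast and smooth muscle (14, miR-145-3p called and 1 adjusted over the list alone; 0.466), −0.46 for endothelial (9; 0.466), −0.28 for erythrocyte (5; 0.507) and 1.26 for skeletal and cardiac muscle (3; 0.493). Fish 38 weighed on several of these: without it the medians were 0.52 for epithelial (adjusted p = 0.748), −0.22 for fibroblast and smooth muscle (0.973) and 0.06 for muscle (then not tested). The leukocyte median was 0.07 with a mean of −0.08 and a test pointing down (adjusted p = 0.802). For the fish interferon-induced pair the median was 0.13 and the mean 0.01 with a test pointing down (7; 0.888), and for stress and hypoxia the median was −0.16 (9; 0.859). The only neural sequence, dre-miR-9-5p, had a change of −1.25 (SE 0.91) and was not tested as a list. With the set as a term the epithelial list passed upward (median 0.83) and the stress and hypoxia list downward, each with adjusted p = 0.0455. The latter is led by fru-miR-21, which then passed too (log2 −1.99, SE 0.46, adjusted p = 0.0401).

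**Figure D2:**
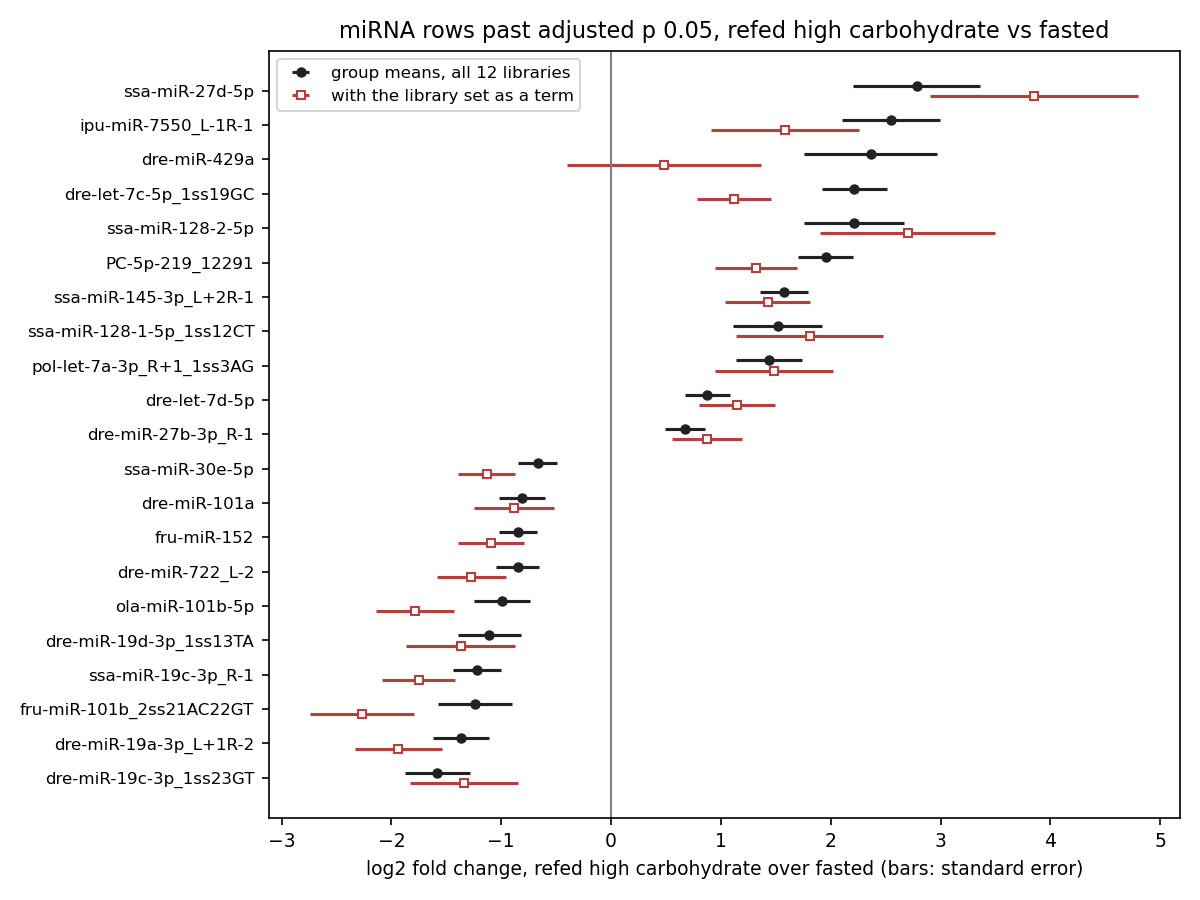
Log2 fold change, highCHO over fasted, of the 21 sequences past adjusted p 0.05 (filled points, bars SE; n = 4 and 4), and the same with the library set as a term (open squares). All 21 keep their sign, and 7 pass with the set as a term.

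The number called in this comparison depended on single libraries: 7 without fasted fish 8, 8 without fasted fish 10, and 13 without fasted fish 7 or highCHO fish 45. Adding the set as a term gave 13, 7 of them among the 21, and with the short-insert percentage as a term 3 passed, ssa-miR-145-3p_L+2R-1, dre-let-7c-5p_1ss19GC and the candidate PC-5p-1744_747 (named after its values were seen; 1102 CPM in highCHO fish 38 and at most 38.2 CPM in the other 11 libraries). Scaling to the sample total gave 13, and leaving out highCHO fish 38 and 49, the libraries with the outlying pancreas sequences and the lowest depth, gave 34, of which 14 were among the 21.

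The third comparison, highCHO against noCHO, sets the meals against each other. The groups also differ in short inserts, miRNA share and library set. ssa-miR-145-3p_L+2R-1 was higher in highCHO fish (9558 ± 1672 against 4189 ± 915 CPM; 2.28-fold, log2 1.19, SE 0.22), as were fru-miR-200a_R-1, an epithelial miRNA (3180 ± 1179 against 1335 ± 180 CPM; 2.38-fold, log2 1.25, SE 0.25), and dre-miR-27b-3p_R-1 (6747 ± 1568 against 3904 ± 433 CPM; 1.73-fold, log2 0.79, SE 0.18). Lower were fru-miR-152 (5307 ± 1211 against 10355 ± 1175 CPM; 1.95-fold, log2 −0.96, SE 0.17), dre-miR-722_L-2 (3963 ± 620 against 8019 ± 1932 CPM; 2.02-fold, log2 −1.02, SE 0.19), dre-miR-19c-3p_1ss23GT (26.7 ± 9.52 against 74.6 ± 8.79 CPM; 2.92-fold, log2 −1.55, SE 0.29) and dre-miR-199-3p_L-1, of connective tissue cells (2307 ± 292 against 3820 ± 282 CPM; 1.66-fold, log2 −0.73, SE 0.15). PC-5p-219_12291 was again higher (log2 1.90, SE 0.25). The other arms did not pass: ola-miR-145_L+1R+4 had a change of 0.04 (SE 0.37) and dre-miR-199-5p one of 0.21 (SE 0.21).

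These 8 sequences, 4 higher and 4 lower, were all that passed (66 at an unadjusted p under 0.05), with adjusted p from 0.00186 to 0.0420. Leaving out each library in 12 fits, dre-miR-27b-3p_R-1 passed in 1, dre-miR-199-3p_L-1 in 4, dre-miR-722_L-2 in 6, fru-miR-152 in 8 and the other 4 in 11 or 12. dre-miR-429a (log2 2.40, SE 0.60) and ssa-miR-128-2-5p (1.73, SE 0.44) had the next smallest p and did not pass (adjusted p = 0.0631 each). Within set 2, with 4 highCHO and 2 noCHO fish, edgeR called 0 (48 at an unadjusted p under 0.05) and all 8 kept their sign: ssa-miR-145-3p_L+2R-1 had 1.14, fru-miR-200a_R-1 1.42, dre-miR-27b-3p_R-1 0.91, fru-miR-152 −1.05, dre-miR-722_L-2 −1.18, dre-miR-19c-3p_1ss23GT −1.39, dre-miR-199-3p_L-1 −0.76 and PC-5p-219_12291 1.63. With the set as a term 18 passed, 7 of the 8 among them; dre-miR-27b-3p_R-1 had adjusted p = 0.0522.

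No list passed between the refed groups with camera. The nearest was miR-17-92 and relatives (median −0.35, 16 of 24 lower, adjusted p = 0.0695; 0.639 with an estimated correlation, 0.0142 with fry), which passed without highCHO fish 45 (0.00931) or 49 (0.0259). In this list 1 was lower over all sequences, and 6 lower and 1 higher adjusted over the list alone. Epithelial miRNAs had a median of 0.96 (adjusted p = 0.450) and passed within set 2 (median 1.60, adjusted p = 0.0446). Pancreas sequences had a median of 3.28, and −0.41 without highCHO fish 38. In the let-7 list the median was 0.18 (adjusted p = 0.516) and no sequence passed, and all 4 miR-122 sequences were lower (median −0.41, smallest adjusted p = 0.137). Calls of single miRNAs fell to 2 without noCHO fish 31, 4 without fasted fish 8 or fasted fish 10 and 5 without noCHO fish 21, and came to 18 without highCHO fish 38. Scaling to the sample total gave 3 (2 higher, 1 lower), and the short-insert term gave 1, PC-5p-1744_747. With that term, which goes together with the highCHO group, the SE of the 8 widened. ssa-miR-145-3p_L+2R-1 then had 1.25 (SE 0.32, adjusted p = 0.0766), fru-miR-200a_R-1 1.28 (SE 0.36, 0.107), dre-miR-19c-3p_1ss23GT −1.71 (SE 0.44, 0.0766) and PC-5p-219_12291 1.38 (SE 0.32, 0.0766). The changes of fru-miR-152 (−0.64, SE 0.24, 0.204), dre-miR-722_L-2 (−0.77, SE 0.28, 0.197), dre-miR-27b-3p_R-1 (0.45, SE 0.25, 0.381) and dre-miR-199-3p_L-1 (−0.59, SE 0.22, 0.215) became smaller.

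**Figure D3:**
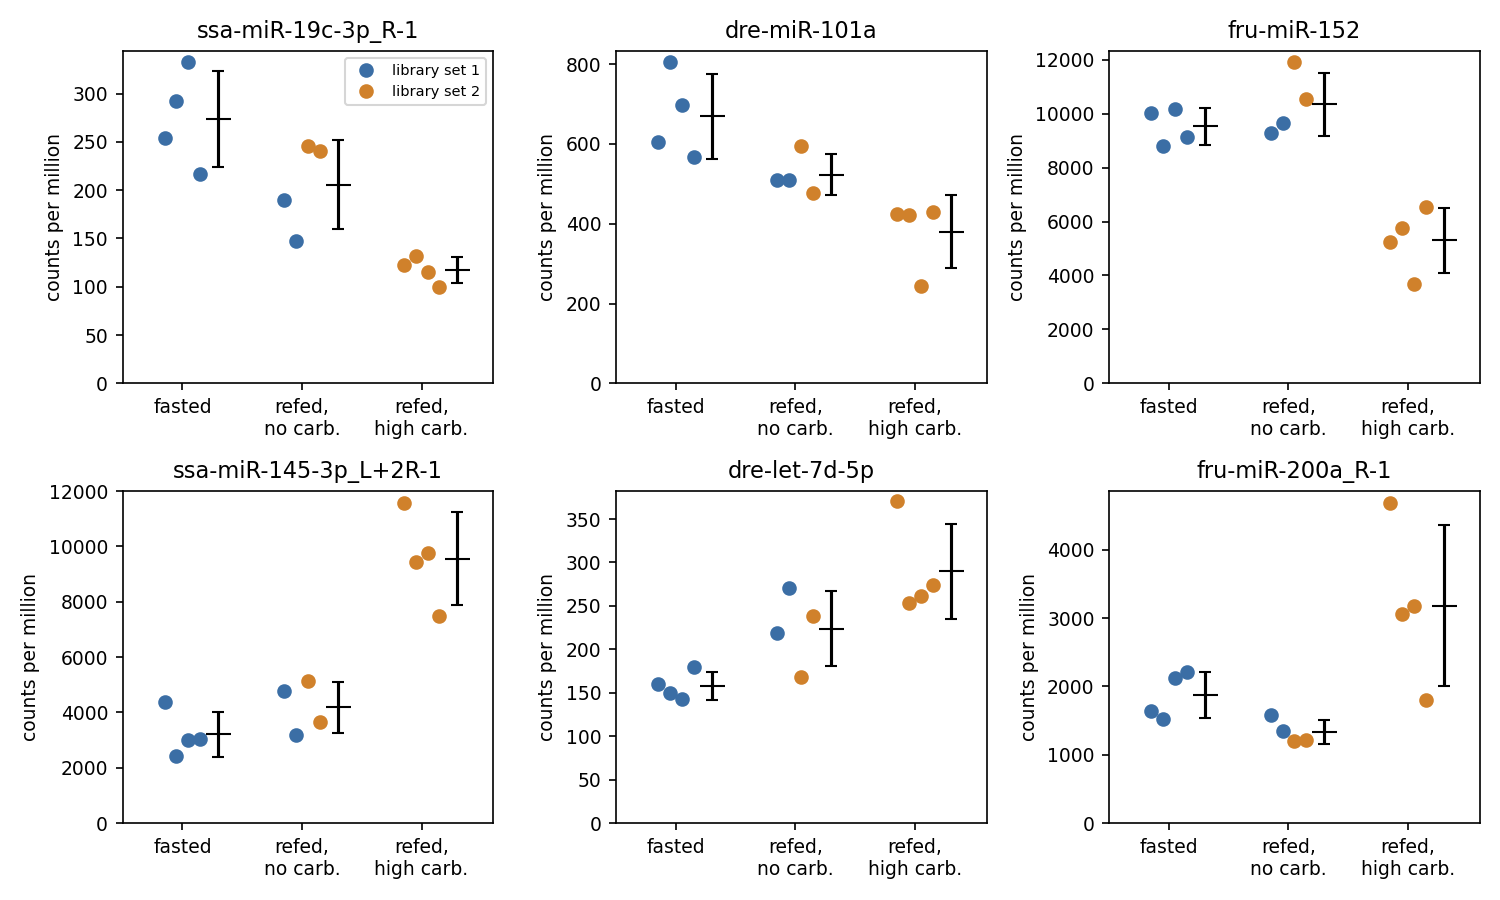
CPM of 6 sequences in each library by group (points, coloured by library set; bars mean and SD, n = 4). dre-let-7d-5p and dre-miR-101a differ between highCHO and fasted; fru-miR-152 falls between noCHO and highCHO from 10355 to 5307 CPM.

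The fourth comparison joins both refed groups against fasted and asks for a response to feeding as such. Higher after refeeding were ssa-miR-145-3p_L+2R-1 (log2 0.98, SE 0.20, adjusted p = 0.0332), ipu-miR-7550_L-1R-1 (2.11, SE 0.40, 0.0332), pol-let-7a-3p_R+1_1ss3AG (1.20, SE 0.27, 0.0456), PC-5p-219_12291 (1.01, SE 0.22, 0.0447) and dre-let-7c-5p_1ss19GC (1.79, SE 0.27, 0.00756; n = 8 refed and 4 fasted for each in edgeR). Lower were ssa-miR-19c-3p_R-1 (−0.82, SE 0.18, 0.0447) and dre-miR-19a-3p_L+1R-2 (−0.90, SE 0.21, 0.0468). ola-miR-101b-5p (−0.85, SE 0.21), dre-let-7d-5p (0.69, SE 0.18) and ssa-miR-128-1-5p_1ss12CT (1.24, SE 0.36) followed without passing. These 7 were all the calls (56 at an unadjusted p under 0.05). In noCHO fish alone none of the 7 passed in edgeR. There PC-5p-219_12291 was not raised (0.06, SE 0.24), and ssa-miR-145-3p_L+2R-1 had 0.38 (SE 0.22), against 1.57 (SE 0.22) in highCHO fish.

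The let-7 list rose (20 of 22 higher, median 0.38, adjusted p = 3.70e-06; adjusted p = 0.274 with an estimated correlation, 0.0417 with fry), with 2 sequences called over all sequences and 3 adjusted over the list alone. The miR-17-92 list fell (18 of 24 lower, median −0.28, adjusted p = 0.00432; adjusted p = 0.274 with an estimated correlation, 0.0256 with fry), with 2 called and 3 adjusted over the list alone. The let-7 list also passed with the set as a term (median 0.61, adjusted p = 1.24e-04) and the miR-17-92 list did not (median −0.34, adjusted p = 0.0921). The latter was also lost without fasted fish 13 (0.0622) or noCHO fish 31 (0.0945). None of the 7 passed with the set as a term, and all kept their sign: ssa-miR-145-3p_L+2R-1 had 0.87 (SE 0.30), ipu-miR-7550_L-1R-1 1.34 (SE 0.52), pol-let-7a-3p_R+1_1ss3AG 1.23 (SE 0.41), PC-5p-219_12291 0.51 (SE 0.29), ssa-miR-19c-3p_R-1 −1.22 (SE 0.27), dre-miR-19a-3p_L+1R-2 −1.34 (SE 0.32) and dre-let-7c-5p_1ss19GC 0.91 (SE 0.26, circular as above). The 1 sequence called with that term was fru-miR-96_R-1, named after its values were seen (log2 2.02, adjusted p = 0.0308). The calls came to 0 without fasted fish 8 or 10, 1 without highCHO fish 45 or 49, 2 without fasted fish 7 or 13, and 3 without highCHO fish 50. They came to 2 without the A19C sequences (ssa-miR-145-3p_L+2R-1 and ipu-miR-7550_L-1R-1), and to 1 under sample total scaling (1 higher, 0 lower) or with the short-insert term, each time dre-let-7c-5p_1ss19GC.

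The responses to the meals were compared across sequences. Log2 changes of noCHO and of highCHO against fasted had a Pearson r of 0.401 over the 340 sequences, which are not independent replicates, and 63.2% had the same sign. Both share the fasted fish: with unchanged groups against the same fasted libraries, 100 simulations gave a mean r of 0.448 (SD 0.103), and with separate fasted fish for each comparison r was −0.05 to 0.37 (mean 0.151 over 6 splits). The covariance was 0.133, against 0.125 simulated. Of the 21 sequences called in highCHO, 17 had the same sign in noCHO, a count to which the shared fasted fish also contribute. Calls in both were 0, which tests nothing, since noCHO against fasted had 0 calls in edgeR. Common direction beyond what the shared fasted fish give was not detectable.

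**Figure D4:**
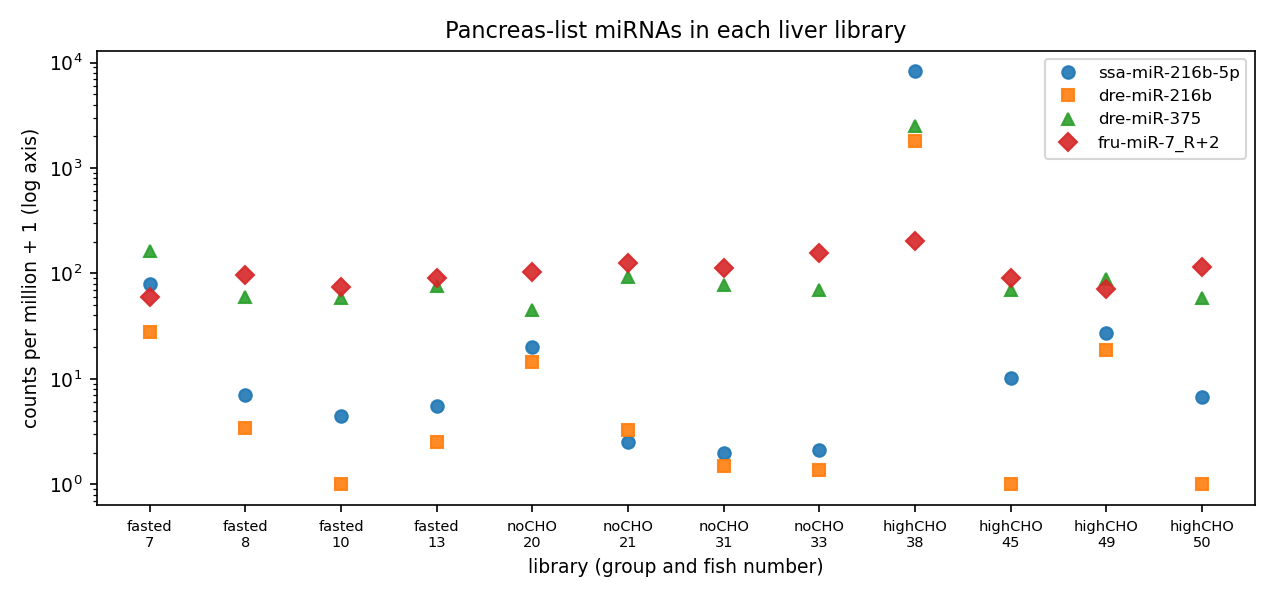
CPM plus 1 (log axis) of the 4 most abundant pancreas-list sequences in each library, labelled by group and fish. In highCHO fish 38, ssa-miR-216b-5p reaches 8261 CPM, against at most 78.6 in the other libraries.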

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

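The comparisons of single libraries with their group followed a rule set in advance; the tests of explanations for the patterns below, all splits of the libraries excepted, were chosen only after the results were seen. A library counted as far from its group when its gap to the nearest of the other 3 took up nearly the whole range of the group (Dixon's 95% limit). Of 294 groups of 4 values, 25 had such a library; chance gives about 5% of groups. Of the 25, 9 were in highCHO fish 38. Values are CPM with the range of the other 3 libraries of the group.

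Pancreas miRNAs stood out in highCHO fish 38: ssa-miR-216b-5p at 8261 (5.73 to 26.5), dre-miR-375 at 2500 (57.3 to 88.4) and dre-miR-216b at 1812 (0 to 17.7). Of the 5 pancreas-list sequences, 1 of which another list also holds, 4 were highest in this library, and together they made up 1.43% of its counts (95% interval 1.41 to 1.45%), against 0.0139 to 0.0354% elsewhere. The high-carbohydrate meal as the cause is argued against: in the other 3 highCHO fish the median log2 difference of these sequences from the 8 fasted and noCHO libraries was −0.12. The 20 hepatocyte sequences had a median log2 difference of 0.29 in fish 38, against −0.35 to 0.16 in the other libraries (SD 0.167). The list thus did not fall as a whole. This cannot decide on a loss of hepatocyte miRNAs, because members diverged and the median does not speak for miR-122. The miR-192 and miR-194 sequences of the list, examined after their values were seen, were each highest in fish 38. They stood at 2.03 to 17.4 times their medians in the other libraries. In fish 38, ipu-miR-192 was 2.51 times its median in the other libraries. There dre-miR-122_R-1 had its lowest share of counts, 22.6%, against 23.4 to 35.7% elsewhere. Pancreatic tissue carried over in dissection may explain the pattern and stays open as a hypothesis, as does an individual difference of this fish, which was not tested.

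The let-7 sequence with the A19C difference, dre-let-7c-5p_1ss19GC, had the smallest p between noCHO and fasted and between both refed groups and fasted, and it divides the libraries into the 2 sets. A response to refeeding is argued against as the whole cause, because the lowest share among the 4 noCHO libraries was 0.971 of the highest fasted share. A candidate explanation is misread let-7 copies in one library set. It predicts the same difference in another abundant let-7: the A19C share of let-7j-like reads was 5.76 times higher in the noCHO libraries of set 2 than in those of set 1, and over all libraries it was 0.0317 ± 0.0202% in set 1 and 0.121 ± 0.0342% in set 2 (SD, n = 6 each) without overlap. In noCHO fish 20 and 21 the share was 0.00670 and 0.0316%, with hhi-let-7j at 8421 and 8472 CPM. At 1.08 and 1.13 M counts these shares rest on few reads, so the ratio is imprecise. The mean A19C share of let-7a-like reads was 1.18% in set 1 and 3.52% in set 2, far above that of let-7j-like reads. Misreading at an equal rate in both let-7 copies does not explain this gap. Of 25 pairs of sequences 1 base apart, 2 differed between sets without overlap, and both were A19C pairs, 1 of which (dre-let-7c-5p_1ss19GC against dre-let-7a) defined the sets. How the sets arose is not given in the labels.

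The other 20 sequences called between highCHO and fasted were set against library quality. Their median log2 change in the direction called was 1.30 (median SE 0.254). With the library set as a term it was 1.40 (SE 0.393; 1.33 to 1.60 leaving out each library), with the short-insert percentage as a term 1.16 (SE 0.367; 1.04 to 1.25), and without highCHO fish 38 and 49 it was 1.26 (SE 0.295; 1.25 to 1.43). All 20 had the same sign each time. The 20 were selected for this change in the same libraries, which favours large values in every fit. The set term rests on the noCHO fish, 2 in each set, and argues against the library set as the whole cause of the median change. Short-insert percentages of highCHO and fasted fish do not overlap, so the fit with that term extrapolates and cannot decide. The fit without highCHO fish 38 and 49 cannot decide, since the sign was nearly fixed by the selection. In 18 of all 21 called sequences every highCHO library lay beyond every fasted library. Their selection in these same libraries makes that likely, and it cannot tell meal from set. The calls numbered 7, 1 and 13 of the 20; with the short-insert term the SE widened and the median change fell little, though single sequences moved more (ssa-miR-27d-5p from 2.78 to 1.18, dre-miR-19d-3p_1ss13TA from −1.11 to −0.41). Short inserts and the highCHO group go together. The meal and a part played by library preparation cannot be separated for single sequences here, and both stay open.

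Other splits of the libraries test how often grouping by chance gives as many calls. Between highCHO and fasted 1 of 35 splits, the real one, gave the 21 miRNAs, and the highest other gave 1. No smaller share is possible with 35 splits, so chance is made unlikely but is not excluded. The real split is also the division by library set, so it does not separate meal from set. Between highCHO and noCHO 1 of 35 splits, the real one, gave 8 or more, and the highest other gave 3. Chance is again made unlikely but is not excluded. Those 8 calls fell to 4 with only the groups compared and to 2 without noCHO fish 31. For both refed groups against fasted 3 of 100 drawn splits gave 7 or more, the real one included, and the highest other, fasted fish 7, 8 and 10 with noCHO fish 31 against the rest, gave 19. Fasted fish 10 with highCHO fish 38, 45 and 49 against the rest also gave 7. Since other splits reached or far passed the real count, these splits cannot exclude chance for the 7 miRNAs. The split with 19 calls points to some structure of the samples, and what sets it apart was not tested.

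Chance cannot be excluded for the numbers of lists called: 16 of 35 splits gave the 2 or more of noCHO against fasted (highest other 5), 10 of 35 the 2 of highCHO against fasted (highest other 4), and 40 of 100 the 2 of both refed groups against fasted (highest other 3). These counts are of lists called and test no single list. Where the real count is 0, every split gives at least as many, so the splits test nothing. This holds for the 0 miRNAs called by edgeR between noCHO and fasted (23 at an unadjusted p under 0.05; 2 by DESeq2), with 35 of 35 splits and 1 in the highest other. It holds also for the 0 lists of highCHO against noCHO by camera (1 by fry), with 35 of 35 and 4 in the highest other.

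In highCHO fish 38, ipu-miR-192 was at 53161 (19169 to 23309), ccr-miR-143 at 26596 (11269 to 12085), ssa-miR-143-5p_R+1 at 194 (79.6 to 86.7), fru-miR-200b_R+1 at 1896 (282 to 532), dre-miR-1 at 160 (8.84 to 11.5) and ipu-miR-29a_R+2 at 20.9 (13.3 to 13.9). In highCHO fish 49, the library with the fewest counts, dre-miR-101a was at 243 (422 to 429), dre-miR-181a-5p at 15684 (9411 to 10011), ssa-miR-222a-3p_R-1 at 2662 (1647 to 1730), dre-miR-499-5p_R-1 at 234 (56.8 to 78.3) and ssa-miR-33a-3p at 106 (24.5 to 36.3). Inserts over 32 nt made up 14.9% of its adapter-containing reads (6.45 to 7.79%). In fasted fish 7, dre-miR-146b_L+1_1ss23GT was at 574 (244 to 263), ssa-miR-216b-5p at 78.6 (3.42 to 5.98), dre-miR-375 at 162 (58.1 to 75.5) and dre-miR-216b at 26.6 (0 to 2.39). In fasted fish 10, dre-miR-181b-5p_R+1 was at 2157 (2849 to 2880). In noCHO fish 31, the erythrocyte miRNAs dre-miR-451_R-1 and fru-miR-144_L+1R-1 were at 2027 (787 to 898) and 1438 (573 to 705), and pol-miR-21-3p_R-1_1ss14AT at 1144 (202 to 350). In noCHO fish 20, ssa-miR-216b-5p was at 19.2 (0.991 to 1.53) and dre-miR-216b at 13.5 (0.364 to 2.29).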

How the results depend on the processing

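The tests with a library set term, within a set, with a short-insert term, without highCHO fish 38 and 49, with the authors' size parameters and without the A19C let-7 sequences were chosen only after the results were seen. Over 416 results for single named sequences and lists, 10061 values under the alternatives stayed on the same side of the threshold. These include values without an adjusted p and values that changed sign where neither fit passed. Most of the 416 results had not passed to begin with. A further 317 values, on 42 results, lost their call, 99 gained one, and 0 changed sign with either value past the threshold. Every sequence and list that passed in the 4 comparisons lost its call under some alternative. The numbers of calls moved more. Where no reason is given, the cause was not tested.

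For noCHO against fasted, the 0 miRNAs of edgeR (23 at an unadjusted p under 0.05) became 4 without the filter and 2 with DESeq2, and 0 to 2 leaving out each library. The 2 lists became 0 with an estimated correlation, 0 with fry, 1 with the set as a term and 1 within set 1, each time let-7, and 1 to 3 leaving out each library.

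For highCHO against fasted, the 21 miRNAs became 13 with sample total scaling, 54 without the filter, 35 with DESeq2, 13 with the set as a term, 3 with the short-insert term and 34 without fish 38 and 49. They were 7 (without fasted fish 8) to 25 (without highCHO fish 49) leaving out each library. The 2 lists became 0 with an estimated correlation, 1 with fry (miR-17-92) and 4 with the set as a term. Leaving out each library gave 2 each time.

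For highCHO against noCHO, the 8 miRNAs became 3 with sample total scaling, 52 without the filter, 22 with DESeq2, 4 with only the groups compared, 18 with the set as a term, 1 with the short-insert term and 23 without fish 38 and 49. Within set 2, with fewer fish, edgeR called 0 (48 at an unadjusted p under 0.05). Leaving out each library gave 2 (without noCHO fish 31) to 18 (without highCHO fish 38). The 0 lists by camera became 1 with sequences summed by name, 1 with fry, 1 within set 2, and 0 to 1 leaving out each library.

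For both refed groups against fasted, the 7 miRNAs became 1 with sample total scaling, 11 with DESeq2, 1 with the set as a term, 1 with the short-insert term and 2 without the A19C sequences. They were 0 (without fasted fish 8 or 10; 34 and 37 at an unadjusted p under 0.05 in edgeR) to 9 (without noCHO fish 31 or highCHO fish 38) leaving out each library. The 2 lists became 0 with an estimated correlation and 1 with the set as a term (let-7), and 1 to 2 leaving out each library.

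The correlation of the responses to the meals, 0.401, was 0.151 with the fasted libraries split between the comparisons and 0.256 at a mean count of at least 100. Leaving out each library gave 0.328 (without highCHO fish 45) to 0.506 (without fasted fish 7).

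Without highCHO fish 38 the muscle list had too few sequences and was not tested. Using only the groups compared gives no value for both refed groups against fasted, since that comparison uses all 12 libraries. At the lowest depth 1 CPM is 0.198 counts, which limits sequences of a few CPM.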
